A study of Mus musculus with 4 samples.

How the data were processed

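FoxO1 ChIP-seq was made from mouse hearts in 3 conditions with 1 library each, and each library came from a pool of 3 hearts, per the labels' protocols. An input library also belonged to the series and was not analysed here. BWA, SICER and the mm10 build are named in the submitters' processing notes, without version or role. Drosophila chromatin was added as a spike-in, per the labels; how values were scaled between libraries is not given in the sources used here.

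The authors deposited a table of regions merged over libraries, with 3 values per library: the mean signal over the region, the peak signal (the highest depth in it) and whether an interval was called. The deposited mean signal is a coverage value: multiplied by the number of 32 bp bins in the region it gave a whole number in 97.4% of Veh/Sham regions (within 0.0005 per bin), against 4.56% for shifted values. Peak values were whole numbers with none missing from 0 to 40, and were treated as depths of overlapping fragments. The deposited table also gives CpG islands, genes and distances to start sites, all used as given; coordinates are those of the table. The table's 6 further columns of values per library, for 2 libraries that match no sample of the series, were not used here. The scaling of deposited signal between libraries is unknown, so shared shifts of the median are given apart from differences relative to it.

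For each pair of libraries, the log2 ratio of mean signal with a pseudocount of 1 was computed per region, which understates the ratio of regions with low signal. A region counted as higher or lower at 1.5-fold, a rule of size and not a test. There were no replicate libraries, so no p-value was computed. Exact 95% counting intervals (Clopper-Pearson) of single ratios come from the 2 peak depths and cover counting error only; fragments without molecular identifiers are not independent molecules, and a peak depth is the highest of several bins. Shares have 95% Wilson intervals. Medians over regions have order-statistic intervals.

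A gene's value was that of its assigned region with the highest mean signal over the 3 libraries; 1 region can be assigned to several genes. For 24 gene lists, the median was placed among the medians of 10000 random lists of the same size, matched on 10 groups of mean signal, as a description of these libraries. Lists outside the central 95% of random lists are named. Of 11718 symbols in the table, 97.2% matched a RefSeq symbol or a unique older symbol of GRCm38.p6. Coverage of lists was compared with random protein-coding genes matched on gene length. Promoter means within 1000 bp of a start site.

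Genes named were, per comparison, the 8 highest and 8 lowest ratios among regions at or above the median mean signal, with 1 region per gene and without predicted symbols; per list, the 2 highest and 2 lowest members; the 10 highest Veh/Sham signals; and Foxo1, Foxo3, Nppa, Nppb and Myh7 whatever their values. List members were named whatever their signal and whether or not their region was called in a library. Regions named per comparison were picked for extreme ratios, so a counting interval that excludes 1 is not a test of them. The mean signal used to choose them included the compared libraries, so a region could pass with little signal in 1 of these. The other cardiac genes named as having no region, and the second Ighg2c region as a TAC signal, were chosen after their values were seen. This rule, the lists, the size rule and the alternatives were fixed before the data were examined, except where the text says otherwise. Alternatives were peak depth, pseudocounts of 5 and 0.1, leaving out the 25% of regions with the lowest signal, recentring on the median, regions called in either library of a pair, a 2-fold rule, and other choices of a gene's region. Forkhead motif density was not analysed here.

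The functions were tested on simulated data. Peak depths were drawn from Poisson distributions for 16126 regions, with 200 regions changed. For TAC against Veh/Sham, the 1.5-fold rule after recentring took 85% of regions raised 2-fold, 76% of those lowered 2-fold, 100% of those raised 4-fold and 94% of those lowered 4-fold, together with 12.6% of unchanged regions as higher. For Iso against Veh/Sham, it took 81% of regions raised 2-fold, 64% of those lowered 2-fold and 13.15% of unchanged regions as higher. Of 50 random lists of 30 genes with no shift, 3 lay outside the central 95% for Iso against Veh/Sham, 2 for TAC against Veh/Sham and 6 for TAC against Iso. With a shift of 0.5 on the log2 scale, 49, 50 and 50 did. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.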

Results

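FoxO1 is a forkhead transcription factor that insulin and growth factor signalling keep out of the nucleus. Its chromatin association in the mouse heart was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in a normal state and in hypertrophy of 2 origins. Male C57BL/6 mice aged 12 weeks received vehicle and a sham operation (Veh/Sham), isoproterenol at 3 mg/kg per day (Iso), or transverse aortic constriction (TAC), each for 7 days. Isoproterenol is a beta-adrenergic agonist, and TAC narrows the aorta and loads the left ventricle with pressure. Hearts of 3 mice were pooled per condition, and each pool gave 1 FoxO1 library. There were therefore no replicate libraries, no spread between replicates and no test across conditions, and every difference given here is a difference between 2 libraries. The deposited table held 16126 merged regions of the mm10 genome with a median length of 409 bp. The median of the mean signal per region was 8.71 in Veh/Sham, 11 in Iso and 13.96 in TAC, and the median peak depth was 12, 16 and 19 overlapping fragments.

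Most merged regions lay at gene promoters. Of the 16126 regions, 8702 (53.96%, 95% Wilson interval 53.2 to 54.7) lay within 1000 bp of a start site and 8727 overlapped a CpG island. Widening the promoter to 5000 bp gave 64.8%. These are shares of regions and not of signal. The input library was not analysed, so no background share stands beside them. The highest Veh/Sham signals were at the promoters of Map3k10, a kinase of the JNK pathway (chromosome 7, 27674475 to 27675190, mean signal 67.3), Rnf44 (chromosome 13, 54693834 to 54695106, 61.9) and Tial1, an RNA-binding protein (chromosome 7, 128461240 to 128462173, 54.9). Ccni, Ncln, Fyco1, Crebl2, Ints9, Abcb8 and Katnal1 followed, with mean signals from 53.0 to 46.6, and all 10 of these regions were called in each of the 3 libraries. The region named for Abcb8 was also assigned to Nos3, the endothelial nitric oxide synthase. The Iso to Veh/Sham ratio of peak depths was 1.16 at Map3k10 (128 and 148, exact 95% counting interval 0.91 to 1.48). It was highest of the 10 at Ints9, with depths of 104 and 141 (ratio 1.36, interval 1.045 to 1.764). Both intervals held 1.27, the Iso to Veh/Sham ratio of peak depths summed over all regions.

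The authors called 7918 regions in Veh/Sham, 5808 in Iso and 7261 in TAC. All 3 libraries shared 3563 regions, and 4916 of the regions were called in none of them. Iso shared 4363 of its calls with Veh/Sham and 4030 with TAC. Calls made in Iso alone (978 regions) lay at promoters in 23.6% of cases (95% Wilson interval 21.1 to 26.4), against 57.2% for calls made in Veh/Sham alone (2171 regions, 55.1 to 59.3) and 51.5% for those in TAC alone (1847 regions, 49.3 to 53.8). Where calls also had to reach the median signal of all called regions, the counts were 1369, 3450 and 5676, so Veh/Sham moved from the most calls to the fewest. At equal signal the libraries also differed: of regions with a mean signal from 12 to below 16, 97.1% were called in Veh/Sham, 57.6% in Iso and 41.6% in TAC. Call counts were therefore not read as amounts of binding.

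Regions covered genes of most lists more often than random genes of similar length: 16 of 24 lists lay above the central 95% of 10000 random lists and 4 below it. Any region counted, also the 4916 called in none of the 3 libraries. With only regions called in Iso, some of the 16 lists lay inside the central 95%. Among them were antioxidant defence (percentile 63.4), cell cycle (80.7), oxidative phosphorylation (81.9) and cardiac transcription factors (84.6). FoxO target genes stayed above it (percentile 100). Of 20008 protein-coding genes, 50.5% had a region. FoxO target genes had one in 39 of 46 cases, autophagy and lysosome genes in 27 of 31, endothelial markers in 25 of 26, cytosolic ribosomal protein genes in 32 of 35, and apoptosis genes in 23 of 25, all among the 16. Markers of other tissues and of blood cells were covered less often: neuronal markers in 3 of 25 cases, liver markers in 6 of 25 and leukocyte markers in 5 of 25 (percentiles 0, 0.10 and 0.11). Sarcomere genes had a region in 10 of 30 cases (percentile 1.62), but lay inside the central 95% without matching on gene length (percentile 3.13). No region was assigned to Nppa, Nppb or Myh7, the natriuretic peptide and slow myosin genes used as markers of hypertrophy, nor to Myh6, Ttn, Ryr2, Atp2a2 or Pln. This coverage comparison was chosen after the data were seen. Its random genes were not matched on CpG islands or expression. Translation factors (25 of 27) and ubiquitin proteasome genes (27 of 30) had a region more often than FoxO target genes. High coverage was therefore not particular to FoxO target genes.

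Foxo1 and Foxo3 themselves held FoxO1 signal. The Foxo1 promoter region (chromosome 3, 52267635 to 52268430) read 13.8 in Veh/Sham, 13.77 in Iso and 19.5 in TAC, and was called in all 3 libraries. The TAC to Veh/Sham ratio of its peak depths, 31 against 19, was 1.63 (exact 95% counting interval 0.89 to 3.06). In mean signal this region had a TAC to Veh/Sham log2 ratio of 0.47, below the median of all regions (0.59). Another Foxo1 region inside the gene (52269361 to 52270123) read 9.21, 7 and 19.8. The highest of 7 Foxo3 regions lay in the gene, 25287 bp from its start site (chromosome 10, 42250998 to 42251913), and read 24.0, 28.7 and 21.2.

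**Figure D1:**
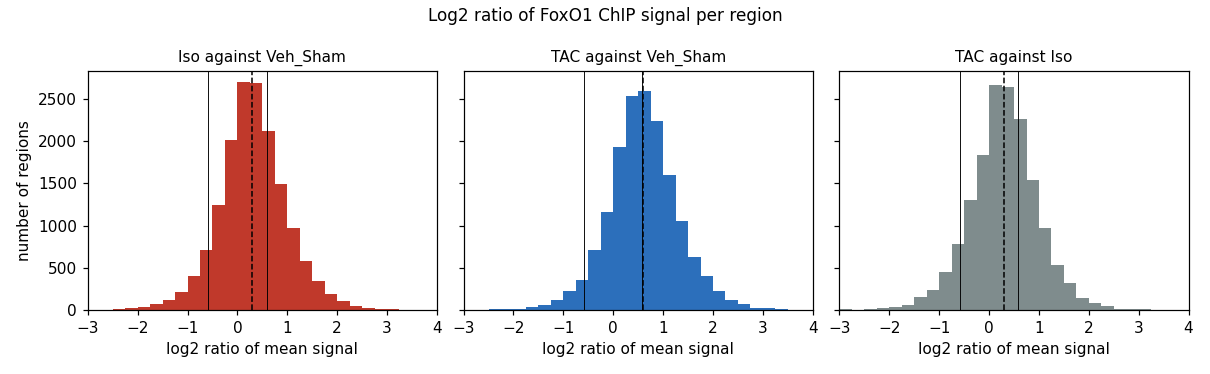
Number of regions by log2 ratio of mean signal (pseudocount 1) for the 3 comparisons, in steps of 0.25 and with the axis ending at -3 and 4. The dashed line marks the median (0.30, 0.59 and 0.29) and the thin lines a 1.5-fold difference; all 3 distributions are shifted to the right of 0.

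Iso was compared with Veh/Sham to see how FoxO1 signal stood after beta-adrenergic stimulation. Signal in Iso was higher over most regions, with a median log2 ratio of 0.30 (1.23-fold, 95% order-statistic interval 0.29 to 0.31). By the 1.5-fold rule, 5129 regions were higher and 1289 lower; relative to the median ratio the split was 2876 to 2596. Among regions at or above the median signal of all regions, called well-covered here, the highest ratio was in Bmpr2, a receptor of bone morphogenetic proteins (chromosome 1, 59797947 to 59798173, inside the gene), where mean signal was 1.71 in Veh/Sham and 25.9 in Iso, and peak depths were 2 and 30 (ratio 15.0, counting interval 3.81 to 129.5). Stk10, a kinase of lymphocytes and other cells (chromosome 11, 32561761 to 32562027), read 2.63 and 21.0, and Phlpp1, a phosphatase of Akt (chromosome 1, 106242156 to 106242412), read 2.25 and 18.1. The Ighg2c region 113287892 to 113288242 on chromosome 12 was listed at 0 in Veh/Sham and read 5 in Iso. It counted as well-covered only through its TAC signal, since that rule used the mean over the 3 libraries. Bmpr2, Stk10 and Phlpp1 also passed with little signal in Veh/Sham, where the median region read 8.71. The highest ratios thus rested on low Veh/Sham values, in regions chosen partly through the compared values. Their counting intervals are no test, since the regions were picked for their ratios. Sema6a, Abhd17a, Tnfrsf1b and Sept9 followed with log2 ratios from 2.51 to 2.29. Of these 8 regions only that of Ighg2c lay within 1000 bp of a start site (865 bp); of all 5129 regions higher in Iso, 37.0% did. Among the same well-covered regions, the lowest ratios were at the promoters of Vhl, the ubiquitin ligase subunit that degrades hypoxia-inducible factors (chromosome 6, 113624100 to 113624352, mean signal 16 and 4, log2 ratio -1.77, peak ratio 0.28 with a counting interval of 0.08 to 0.78), and Lmnb2, a nuclear lamin (16.3 and 4.63, log2 ratio -1.62). Zbtb7b, Mxi1, Zfp322a, Mn1, Pdcd2l and Nfib had log2 ratios between -1.54 and -1.30.

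FoxO target genes stood below random lists in Iso. Of 39 members with a region, 2 were at least 1.5-fold higher, 4 at least 1.5-fold lower and 33 in between; relative to the median of all regions, 2 were higher and 8 lower. Their median log2 ratio was 0.00, below the range of 0.11 to 0.42 that held 95% of random lists matched on signal (percentile 0.06). The lowest members were Klf4 (-0.85) and Irs2, an adaptor of the insulin receptor (-0.68), and the highest were Sesn3, a stress-induced sestrin (1.61), and Sod2, the mitochondrial superoxide dismutase (0.93). The Sod2 region was called in none of the 3 libraries, with peak depths of 15 in Veh/Sham and 29 in Iso. With the mean over all regions of a gene in place of its highest region, the percentile of the FoxO list was 33.75. Genes of glucose uptake and glycolysis had a median of -0.01 (percentile 0.78), with 2 of 26 higher and 1 lower (1 and 6 relative to the median of all regions); the lowest were Slc16a1, a lactate transporter (-0.73), and Pygm, muscle glycogen phosphorylase (-0.55). The Slc16a1 region was called in none of the 3 libraries, with peak depths of 8 in Veh/Sham and 5 in Iso. The glycolysis list moved to percentile 63.3 with called regions only and 35.2 without the 25% of regions of lowest signal. It moved to 34.2 with the mean over all regions and 12.5 with the region nearest the start site. Oxidative phosphorylation genes had a median of 0.00 (percentile 1.15), with 3 of 30 higher and 3 lower (1 and 6 relative to the median), from Ndufa4 (-0.98) to Ndufv1 (0.92). That list moved to percentile 4.83, 14.1 and 9.25 with called regions only, the mean over all regions and the region nearest the start site, and to 2.54 with random lists matched also on CpG islands, a setting chosen after the data were seen. In the original setting all lists but these lay within the central 95% of random lists, and chance puts 1.2 of 24 lists outside it. In the antioxidant list, Mt1 and Mt2 shared 1 region (log2 ratio 0.95) and Ucp2 and Ucp3 another (1.26), so each region counted for 2 genes. With peak depths, antioxidant defence (percentile 98.2) and endothelial markers (1.85) also lay outside. Translation factors did with called regions only (1.51) and with the region nearest the start site (2.13). Cardiac transcription factors did with a pseudocount of 5 (97.55). Among the other lists, the highest sarcomere members were Tnni3, cardiac troponin I (2.11), and Des, desmin (1.57). The Tnni3 region lay 12354 bp from its start site and read 3.60 in Veh/Sham and 18.9 in Iso. The Des region was called in none of the 3 libraries, with peak depths of 3 in Veh/Sham and 10 in Iso. Autophagy genes ranged from Wipi2 (-1.02) to Atg5 (1.65), and cardiac transcription factors from Hand2 (-0.49) to Nfatc3 (1.29).

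TAC was compared with Veh/Sham to see how FoxO1 signal stood after pressure overload. Signal in TAC was higher over most regions, with a median log2 ratio of 0.59 (95% order-statistic interval 0.58 to 0.60). By the 1.5-fold rule, 8103 regions were higher and 674 lower; relative to the median ratio the split was 2968 to 2736. The 3 highest mean signals of the TAC library lay at immunoglobulin constant genes: Igkc, the kappa light chain (chromosome 6, 70726320 to 70726865), read 3.94 in Veh/Sham, 12.8 in Iso and 133.9 in TAC (TAC to Veh/Sham peak ratio 39.0, counting interval 17.7 to 107). This region lay over the Igkc exon (70726435 to 70726754 in RefSeq). Ighg1, a heavy chain gene (chromosome 12, 113328871 to 113329836), read 121.1 in TAC and was listed at 0 in Veh/Sham, and 2 regions of Ighg2c (113287892 to 113288242 and 113288540 to 113289043) read 52.1 and 98.0 in TAC. Among the other well-covered regions, the highest ratios were at Fam131a (2.80), Stk10 (2.79), Smagp (2.78), Psmd2, a proteasome subunit (2.75), and Palmd (2.71). The Fam131a region was also assigned to the translation factor Eif4g1. The lowest ratios of well-covered regions were in Cyp2c44, a cytochrome P450 (chromosome 19, 44021600 to 44021893, 12.4 and 2.7, log2 ratio -1.86, peak ratio 0.22 with a counting interval of 0.06 to 0.68), Htra3, a secreted serine protease (-1.72), Zfp280d (-1.31), Htra1 (-1.29), Abca1, the cholesterol exporter (-1.28), Nav1, Cul2 and Oxr1.

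No gene list stood apart from random lists in TAC, although single members were well above the median. None of the 24 lists lay outside the central 95% of random lists; the FoxO target list did with peak depths (percentile 2.37), liver markers did without the 25% of regions of lowest signal (0.40, 4 genes). With the mean over all regions of a gene, insulin and growth factor signalling lay below (1.91) and cardiac transcription factors above (98.4). FoxO target genes had a median of 0.41 (percentile 13.9), with 13 of 39 at least 1.5-fold higher and 2 lower; Cdkn1b, the cell cycle inhibitor p27 (1.31), and Ddit4, an inhibitor of mTOR signalling (1.10), were highest, and Eif4ebp1 (-0.82) and Insr, the insulin receptor (-0.63), lowest. The Ddit4 region was called in none of the 3 libraries, with peak depths of 9 in Veh/Sham and 17 in TAC. Relative to the median of all regions, 1 of the 39 FoxO target genes was higher and 7 lower. Cardiac transcription factors had a median of 0.71 (percentile 78.2), with 13 of 21 higher and 0 lower (6 and 1 relative to the median), led by Srf, serum response factor (1.72), and Nfatc1, a calcineurin effector (1.67). Apoptosis genes had a median of 0.66 (percentile 90.5), with 13 of 23 higher and 1 lower (5 and 2 relative to the median). They were led by Apaf1, the scaffold of the apoptosome (2.10), and Bid (1.94). Cell cycle genes included Ccnb1, cyclin B1 (3.20), where peak depths were 2 in Veh/Sham, 3 in Iso and 22 in TAC. Fetal and hypertrophic stress genes had a median of 0.78 (percentile 93.8). Of 12 members with a region, 9 were higher and 3 lower, but 1 and 3 relative to the median. Meox1 (1.92) and the immediate early gene Fos (1.10) were highest and Timp1 (-1.67), whose region was shared with Syn1, lowest. Endothelial markers had a median of 0.43 (percentile 31.3), with 9 of 25 higher and 0 lower, but 2 and 4 relative to the median. Erg, an endothelial transcription factor (1.45), and Egfl7 (1.18) were highest.

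**Figure D2:**
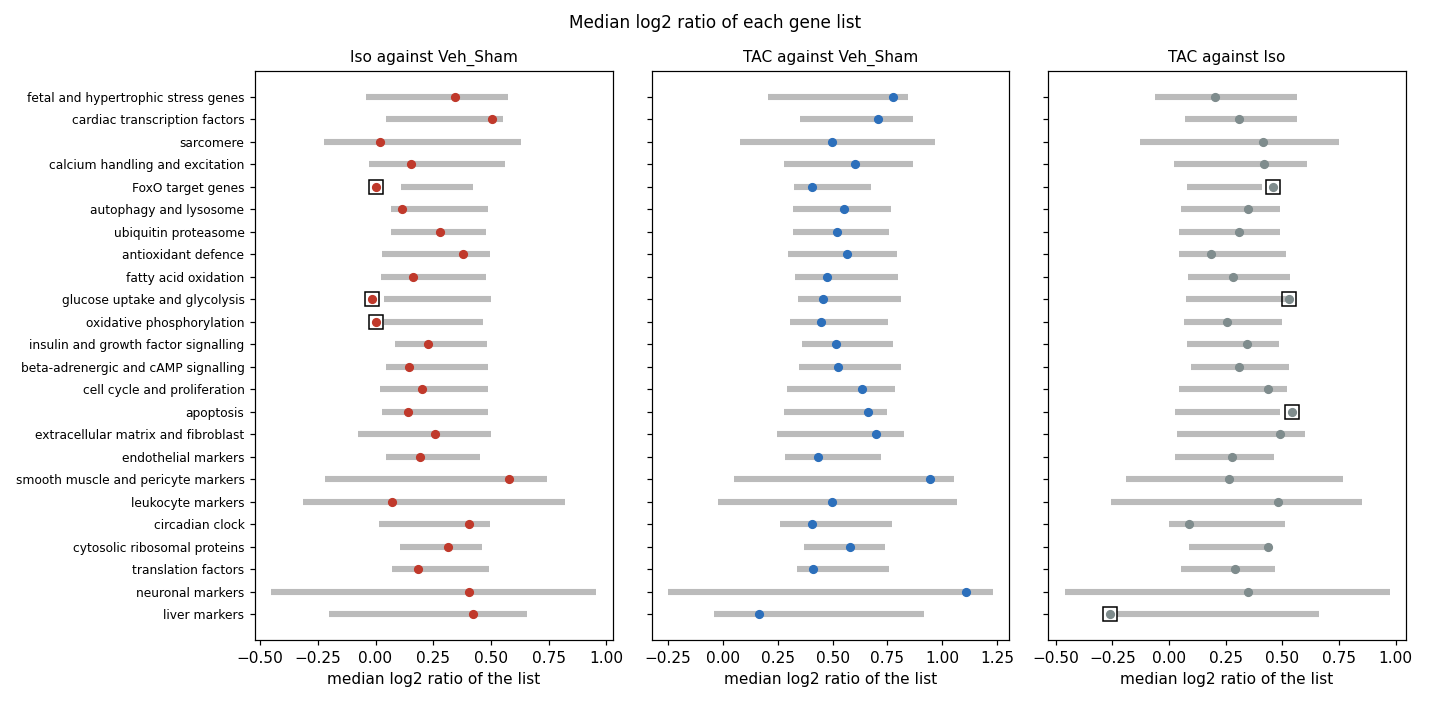
Median log2 ratio of each of 24 gene lists (points) for the 3 comparisons, with the grey bar holding 95% of the medians of 10000 random lists matched on signal. Squares mark the lists outside that range: 3 in Iso against Veh/Sham, 0 in TAC against Veh/Sham and 4 in TAC against Iso.

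TAC was compared directly with Iso because the comparisons against Veh/Sham share 1 library. This comparison in turn shares the Iso library with Iso against Veh/Sham and the TAC library with TAC against Veh/Sham. Genes named in more than 1 comparison, such as Mn1 and Cyp2c44, therefore rest partly on the same value and are not independent agreement. Signal in TAC was higher over most regions (median log2 ratio 0.29, 1.23-fold), with 5065 regions at least 1.5-fold higher and 1427 lower; relative to the median ratio the split was 2738 to 2807. Among well-covered regions, the highest ratios after the immunoglobulin genes were at Mn1, a transcriptional coregulator (chromosome 5, 111416657 to 111416923, 2.88 in Iso and 23.6 in TAC, peak ratio 7.00 with a counting interval of 2.45 to 27.5), Poli, a DNA polymerase (3.82 in Iso and 26.2 in TAC), and the mitochondrial genes Ndufaf4 (log2 ratio 2.34) and Minos1 (2.31). The lowest of these regions were at Cyp2c44 (-2.57), Oxr1 (-2.45), Htra3 (-2.38), Abca1 (-1.94), Vwa8 (-1.88), Htra1 (-1.81), Mill2 and Arhgef6. FoxO target genes stood above random lists (median 0.46, percentile 99.2, 13 of 39 higher and 4 lower, but 5 and 8 relative to the median of all regions), from Irs2 (mean signal 5.70 in Iso and 18.0 in TAC) and Ddit4 (log2 ratio 1.10) to Insr (-1.14). So did apoptosis genes (median 0.54, percentile 99.2, 9 of 23 higher and 0 lower, 3 and 2 relative to the median), led by Tradd, an adaptor of the tumour necrosis factor receptor (1.58), and genes of glucose uptake and glycolysis (median 0.53, percentile 97.85, 9 of 26 higher and 1 lower, 3 and 2 relative to the median), led by Gapdh (1.08). The FoxO and glycolysis lists were low in Iso against Veh/Sham and inside the central 95% in TAC against Veh/Sham (percentiles 13.9 and 18.2), so their standing in both other comparisons rested on the same Iso values. Liver markers, with 6 genes, stood below (median -0.26, percentile 1.81), with Fgb lowest (-0.98). Chance puts 1.2 of 24 lists outside the central 95%. Of 50 random lists with no shift, 6 lay outside in this comparison. The Ddit4 region named above was called in none of the 3 libraries, with peak depths of 6 in Iso and 17 in TAC. With peak depths the FoxO, glycolysis and apoptosis lists lay inside the central 95%, at percentiles 92.5, 80.7 and 81.7, and with called regions only all 4 lists did (FoxO 96.1, glycolysis 96.1, apoptosis 97.03, liver 3.26). FoxO and apoptosis genes also moved inside with the mean over all regions of a gene (55.3 and 92.9) and the region nearest the start site (96.1 and 96.6). Glycolysis genes moved to 46.9 without the 25% of regions of lowest signal and to 95.5 with a pseudocount of 5, and with random lists matched also on CpG islands glycolysis (95.9) and liver (2.51) moved inside.

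The ratio of TAC to Iso depended on CpG islands. Promoter regions with a CpG island had a median log2 ratio of 0.41 (7541 regions) and those without one 0.21 (1161 regions). Outside promoters the medians were 0.49 with a CpG island (1186 regions) and 0.09 without (6238 regions). For Iso against Veh/Sham the order was turned: 0.15 and 0.39 at promoters, 0.13 and 0.56 outside them. TAC against Veh/Sham differed little by CpG island, with 0.55 and 0.58 at promoters and 0.62 and 0.64 outside them, so the dependence was seen in the comparisons that hold the Iso library.

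**Figure D3:**
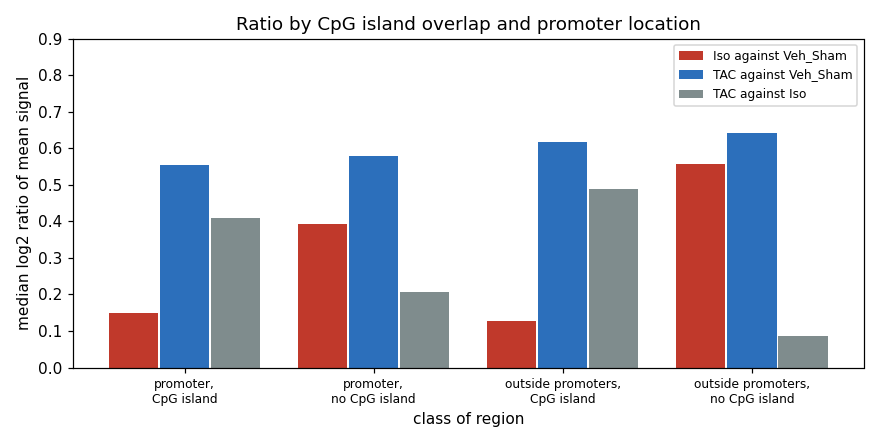
Median log2 ratio of mean signal for the 3 comparisons in regions at and outside promoters, with and without a CpG island; bars are medians over regions of 1 library pair and carry no replicate error. TAC to Iso bars are 0.41, 0.21, 0.49 and 0.09 from left to right.

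Across the 16126 regions, log2 ratios of Iso and TAC against the shared Veh/Sham library correlated with Pearson's r of 0.51 and Spearman's rho of 0.49; regions are not independent replicates. With peak depths r was 0.50, and simulated unchanged regions with counting noise alone gave 0.57, since both ratios hold the same Veh/Sham value. The covariance was 0.23 against 0.17 simulated, a difference of 0.06. By the 1.5-fold rule on peak depths, 3972 regions were higher in both comparisons, against 3708 in simulated unchanged libraries with the shared control and 2703 for independent lists. Lower in both were 229, against 89.1 simulated and 51.7 for independent lists. Relative to the median ratios, 1290 were higher in both (1027 simulated, 492 for independent lists) and 941 lower in both (642.9 and 419.3). Veh/Sham was 1 library and could not be split, so part or all of the overlap beyond independent lists may come from sharing it. Counting noise also put many single regions past the size rule. Relative to the median ratio of peak depths, simulated unchanged libraries gave 2066 higher and 1953 lower regions for Iso against Veh/Sham, 2049 and 1918 for TAC against Veh/Sham, and 1774 and 1747 for TAC against Iso. The observed counts were 2788 and 2565, 2846 and 2636, and 2862 and 2837. Simulated unchanged libraries also put 259.3 regions above and 271.4 below the exact counting interval for Iso against Veh/Sham (629 and 614 observed). For TAC against Veh/Sham they put 252 above and 243.15 below (752 and 730 observed), and for TAC against Iso 260.35 and 267.8 (934 and 1020). An interval that excludes 1 is therefore no test of a region picked for its ratio.

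**Figure D4:**
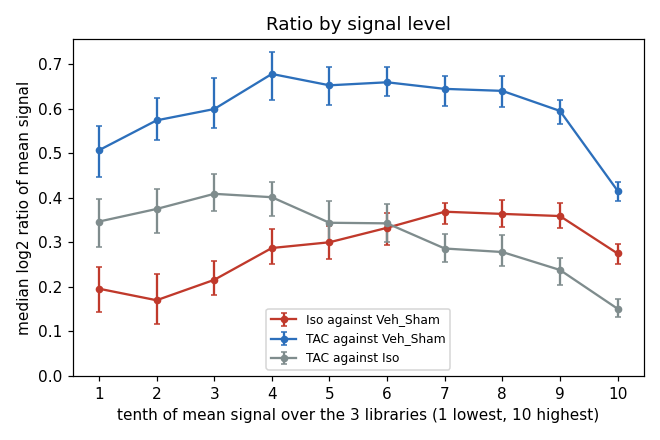
Median log2 ratio of mean signal in 10 groups of regions ordered by mean signal over the 3 libraries, with bars for the 95% bootstrap interval over regions. TAC against Veh/Sham runs from 0.51 in the lowest group over 0.68 in the fourth to 0.42 in the highest.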

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

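The comparison of random lists matched also on CpG islands, list coverage without length matching, and the alternatives for the CpG island difference were chosen after the data were seen. No paired analysis was possible because each condition had 1 library. Forkhead motif density was not run, since no genome was used here. The median ratio stayed above 0 in all 3 comparisons under every alternative tried except recentring, which sets it to 0. Values below follow the order Iso against Veh/Sham, TAC against Veh/Sham, TAC against Iso, and the cause was not tested unless the setting itself gives it.

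Recentring on the median set higher and lower counts to 2876 and 2596, 2968 and 2736, and 2738 and 2807, by construction. A 2-fold rule gave 2287 and 477, 4153 and 228, and 2122 and 532, also by construction. Regions called in a compared library gave 2518 and 826, 4757 higher, and 2966 and 885, with fewer regions counted. A pseudocount of 5, which shrinks ratios by construction, gave 3262 and 618, 327 lower, and 888 lower. Leaving out the 25% of regions of lowest signal gave 665 lower in Iso and 319 lower in TAC than Veh/Sham, with fewer regions counted.

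Median log2 ratios were 0.32, 0.55 and 0.22 with peak depths, 0.22, 0.44 and 0.23 with a pseudocount of 5, and 0.33, 0.64 and 0.32 with 0.1. They were 0.35, 0.66 and 0.33 without the regions of lowest signal and 0.22, 0.53 and 0.31 with called regions only. The correlation of the Iso and TAC ratios was 0.50 with peak depths, 0.46 and 0.55 with pseudocounts of 5 and 0.1, and 0.44 without the regions of lowest signal. Calls that also reached the median signal of called regions numbered 1369 in Veh/Sham, 3450 in Iso and 1024 in all 3 libraries. The promoter share was 64.8% within 5000 bp and 65.4% in the 25% of regions of highest signal.

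The number of gene lists outside the central 95% of random lists was 5 with peak depths and 1 with the mean over all regions of a gene for Iso against Veh/Sham; the latter was the insulin signalling list, not a list named for the original setting. For TAC against Veh/Sham it was 1 with peak depths, 1 without the regions of lowest signal and 2 with the mean over all regions (insulin signalling, at -0.23 from random lists, and cardiac transcription factors, at 0.28). Coverage of sarcomere genes moved inside without length matching (percentile 3.13). For TAC against Iso it was 1 with peak depths, 2 with called regions, 2 with the region nearest the start site and 2 with random lists matched also on CpG islands. The 2 with called regions were the cell cycle (percentile 99.9) and ribosomal protein lists (99.3), and none of FoxO, glycolysis, apoptosis and liver. The FoxO target list in Iso stayed outside under all of these settings except the mean over all regions, where its distance from random lists was -0.04. Relative to random lists, the glycolysis list turned to 0.039 for Iso against Veh/Sham with called regions and to -0.0092 for TAC against Iso without the regions of lowest signal. Cardiac transcription factors turned to 0.24 for TAC against Iso with the mean over all regions, and Ctgf turned to -0.093 for TAC against Iso with peak depths. Across the other list and setting pairs, 544 kept their side, 22 moved inside, 14 moved outside and 65 changed side of 0 within the central 95%. The 544 include 72 pairs from recentring, which shifts lists and random lists alike and so could not move them. Peak depths of 12, 16 and 19 at the median region limit single ratios, as the counting intervals show.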

Other observations

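The tests of explanations below were chosen after the result was seen, except that of signal level for the CpG island pattern.

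Genes of insulin and growth factor signalling had 13 of 29 members at least 1.5-fold higher in TAC than in Veh/Sham and 3 lower (6 and 4 relative to the median of all regions), with Ptpn1, a phosphatase of the insulin receptor (log2 ratio 1.53), and Akt1 (1.45) highest; the list median of 0.52 lay at percentile 34.4 of random lists, but with the mean over all regions of a gene the list lay at 1.91. Beta-adrenergic and cAMP signalling genes had 12 of 31 higher and 2 lower, but 4 and 5 relative to the median (percentile 34.9), from Prkar1a, a regulatory subunit of protein kinase A (1.80), to Pde3a (-1.07). Extracellular matrix genes had 12 of 22 higher and 3 lower, but 4 and 5 relative to the median (percentile 86.3), with Ctgf (1.64) among the highest and Tgfbr1 (-1.16) among the lowest. Smooth muscle and pericyte markers had 3 of 7 members higher in Iso and 4 of 7 in TAC (2 and 3 relative to the median, percentiles 90.2 and 94.3), and 1 lower in each, Notch3 (-1.86 and -1.60, both against the same Veh/Sham value). Cytosolic ribosomal protein genes had 13 of 32 higher and 0 lower in TAC than in Iso, but 3 and 4 relative to the median (percentile 95.9).

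The 4 immunoglobulin constant regions read a median of 108.8 above scaled Veh/Sham signal in TAC. Chromatin of B lineage cells in the TAC hearts stays open: signal added at B lineage genes had a median of -0.589 (95% bootstrap interval -7.45 to 3.78, 10 of 30 genes with a region, 2 of the 30 also in the leukocyte list), but single genes went both ways, from -9.43 at Sdc1 to 14.4 at Prdm1. DNA holding the coding sequence of the constant regions from outside the heart chromatin also stays open. The centre of the Igkc region lay -2 bp from the centre of the Igkc exon. Signal on this gene from B lineage chromatin could lie there too, so the distance cannot separate these sources. That distance had been seen before it was tested and concerns 1 region. A difference of the TAC hearts themselves stays open as untested.

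The TAC to Iso ratio was higher at CpG islands, and the Iso to Veh/Sham ratio lower, while TAC to Veh/Sham medians differed little (0.55 and 0.58 at promoters), so the pattern followed the Iso library. Location at promoters could not be the whole cause, since outside promoters regions with a CpG island lay 0.401 above the others on the log2 scale (95% bootstrap interval 0.354 to 0.445). Signal level could not be the whole cause either, since the median difference over 10 signal groups was 0.364 (range 0.226 to 0.411). Base composition was not analysed here and may contribute, as may a difference between the hearts of the 2 models, which stays untested.

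Signal was higher in Iso and TAC than in Veh/Sham while fewer regions were called. A single scale factor would give 1 ratio at all signal levels if regions were not selected by their signal. In 10 groups ordered by Iso signal, the top group lay at -0.252 relative to the middle groups in log2 ratio of TAC to Veh/Sham (95% bootstrap interval -0.291 to -0.216). Regions called in TAC alone had a median log2 ratio of 1.43, and those called in Veh/Sham alone -0.07. If regions entered the merged set through calls, that selection could itself bend the ratio. The test therefore cannot decide, and a single scale factor stays open. A constant background stays open: the signal added in TAC in the top group was 1.361 times that in the second-lowest group (1.23 to 1.49) and 1.69 times that in the lowest (1.5 to 1.85). A mix of both, and a biological difference between the conditions, stay open as untested.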
